A study of Caenorhabditis elegans with 4 samples.

How the data were processed

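Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers DNA bound by a protein from cross-linked, sheared chromatin, and peaks are stretches of the genome where the recovered DNA is enriched. The samples were Caenorhabditis elegans embryos of mixed stages and both sexes, of the wild-type N2 strain. The antibody was an affinity-purified rabbit polyclonal serum raised against SMC-6, a subunit of the SMC-5/6 complex, which belongs to the same protein family as condensin and cohesin. Per the labels' protocols, embryos were released by bleaching, fixed with formaldehyde and frozen, and their extracts were sonicated. A part of each extract was kept as input DNA.

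The series held 2 ChIP libraries and 2 input libraries, each numbered replicate 1 and replicate 2. Sample groups and replicate numbers were taken from the sample titles. Each ChIP library had its own peak list, and 1 further list covered the whole series. Input libraries entered no comparison here, because no peak list or signal of theirs was analysed. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical.

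Reads were aligned with BWA, version not given in the sources used here, and the build was ce10, per the submitters' processing notes. Coordinates were on WormBase WS220 (the same assembly as ce10), per the file headers, and are given 1-based. The replicate lists were called with MACS and the series-wide list with MACS v2, per the files' own source field. How the 2 ChIP libraries were joined for the series-wide list, and which input each call used, is not given in the sources used here.

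The deposited value of each peak is the authors' score from the peak caller. No header gives its scale. The lowest score was 1.31 in the series-wide list, 50.01 in replicate 1 and 50.04 in replicate 2, so scores of the series-wide list were never compared with those of the replicate lists. In the replicate lists many peaks tied at a score of 3100, with 18 such peaks in replicate 1 and 28 in replicate 2. The first and last base of each peak are other deposited values, used as given. Read numbers and sequencing depth are unknown from these lists, so no count test was run. A peak missing from a list was not called there, which is not evidence that the site was unbound.

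Peaks on the 6 nuclear chromosomes were analysed, and mitochondrial peaks were set apart. Chromosome length was taken as the last base of any listed peak, except in the test of peaks at chromosome ends, which used the WS220 lengths from general knowledge of that assembly. Lists were compared by overlap of at least 1 bp. Chance overlap came from 1000 circular shifts of 1 list along each chromosome, with a one-sided p. Scores of shared peaks were compared with 1 partner per peak, the one with the longest overlap, by Spearman's rho and Pearson's r with 100000 permutations.

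Densities on X against the 5 autosomes were compared as ratios of peaks per Mb. Each autosome was also divided into 3 parts of equal length, and the density in the left and right parts (the ends) was set against that in the middle part (the centre). Each chromosome was divided into blocks of about 500 kb, blocks were permuted between the classes 100000 times for a two-sided p, and 10000 bootstrap resamples of blocks gave the 95% interval. Whether a ratio differed between the replicate lists was tested on the quotient of their ratios, by the same bootstrap and by permuting block classes on the difference of block shares. Clustering was the share of peaks with a neighbour within 10 kb, against 1000 random placements of the same widths without overlap. Widths were compared by permuting ranks 100000 times. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat peaks as independent. These tests are over peaks or blocks of 1 genome, not over biological replicates. Benjamini-Hochberg adjustment covered 16 tests.

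Before the data were examined, the main comparisons, their alternatives and the rule for named regions were fixed. The direct tests of the difference between the replicate lists, the ratios for peaks with and without a partner and by width, the overlap of peaks of 2 kb or more and the leaving out of each autosome were chosen after the data were seen. Named regions were the 10 highest-scoring peaks of the series-wide list among those overlapped by both replicate lists, and the highest-scoring and the widest such peak of each chromosome. Alternatives were overlaps of 50% of the smaller or of both peaks, the upper 50% of each list by score, equal list sizes, each replicate list alone, peaks in both replicate lists, covered bases, merging of peaks under 1 kb apart, blocks of 1 Mb, narrower ends against a wider centre, and windows of 5 and 20 kb.

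The planned comparisons with transcription start sites, gene features, non-coding RNA genes, gene lists and base composition were not run. The gene table at hand is of the WBcel235 assembly, and coordinates of different builds were not mixed. Regions are therefore given by position, without gene assignments.

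The procedures were tested on simulated lists. Of 100 pairs of independent lists of the size of the replicate lists, 2 passed a p of 0.05 for overlap. With 3392 simulated peaks, a true X ratio of 1.5 was recovered as 1.49 on average and called in 100 of 100 simulations, against 4 of 100 with no difference. A true end to centre ratio of 1.3 was recovered as 1.29 and called in 100 of 100, against 9 of 100 with no difference. In these simulations of X and of ends, peaks were placed independently of one another and outnumbered those of either replicate list. The real peaks lay in groups, so these rates need not hold for the real lists, least of all for the replicate lists. Unclustered lists passed in 4 of 100. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.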

Results

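To map where SMC-6 is bound along the chromosomes of C. elegans embryos, SMC-6 ChIP was carried out in 2 libraries, with 2 input libraries beside them. The list of replicate 1 held 2068 peaks, that of replicate 2 held 1430, and the series-wide list held 3392. On the 6 nuclear chromosomes these came to 2065, 1427 and 3380 peaks, or 20.6, 14.2 and 33.7 peaks per Mb. Peaks were mostly short. The median width was 298 bp in replicate 1, 446 bp in replicate 2 and 266 bp in the series-wide list. Together the peaks covered 0.969% of the nuclear genome in replicate 1, 0.866% in replicate 2 and 1.29% in the series-wide list. Replicate 2 peaks were wider than replicate 1 peaks (permutation test of ranks, p = 1e-05, the smallest these permutations can give; adjusted p = 2.7e-05).

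The highest-scoring series-wide peaks among those called in both libraries were sharp, under 1 kb wide, and lay on chromosomes I, II, III and V, several of them next to each other. On chromosome II, a peak at 10034508 to 10035095 had the highest score of all, 271, and its neighbour at 10033374 to 10034002 scored 270.1. Another group on the same chromosome lay at 5346325 to 5346975 (score 263) and 5350135 to 5350776 (score 270.1). Chromosome I held an adjacent pair at 6722986 to 6723599 (score 271) and 6724082 to 6724803 (score 270.1). The right end of chromosome III held peaks at 13292462 to 13293427 (score 260.4) and 13296018 to 13296615 (score 255), and a further peak lay at 4568395 to 4568933 (score 268). On chromosome V the highest peak lay at 14038232 to 14039001 (score 271). Chromosome IV peaked at 390199 to 390793 (score 240.4) and X at 9296567 to 9296958 (score 169). All 10 of the highest-scoring sites had a score of 3100 in replicate 2, the tied value. In replicate 1 their median score was 1038 and they ranked 65 to 136, so they were not the top of that list. These peaks were between 539 and 966 bp wide. Scores are the authors' own.

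The widest shared peaks were a different set of regions. An 11157 bp peak covered positions 15060218 to 15071374 at the right end of chromosome I, the chromosome end that carries the tandem array of ribosomal RNA genes. It was called with nearly the same borders in both libraries, 15060222 to 15071349 in replicate 1 and 15060226 to 15071351 in replicate 2. Input signal there was not analysed, so an effect of reads from repeats on this peak cannot be told apart from binding. Without an annotation of the same build the position of those genes was not compared with it. Chromosome IV had a 6638 bp peak at 8575102 to 8581739, and chromosome V a 6547 bp peak at 3434551 to 3441097. The widest shared peak of chromosome III spanned 5501 bp (5353036 to 5358536), that of X 5357 bp (289874 to 295230) and that of chromosome II 4442 bp (8288313 to 8292754). Their scores in the series-wide list were lower than those of the sharp peaks, between 13.68 on X and 51.97 on chromosome I. In replicate 1 the order was the other way except on X. Replicate 1 peaks in these regions scored 3100 on I, III, IV and V and 2177 on II, against 704 to 1447 at the 10 highest-scoring sites. Replicate 2 peaks there scored 3100 on I and II, 3062 on III and 1614 on IV, against 3100 at each of the 10 sites. On I and II the wide regions thus matched the sharp sites in replicate 2. The IV region was divided into 4 peaks in replicate 1 and 3 in replicate 2, so neither library called it as a single peak. Replicate 1 had 2 peaks in the II region, and replicate 2 had 2 in the III region. The V peak was called as a single peak in each library, with a score of 3100 in replicate 1 and 356 in replicate 2. The X region was wide in replicate 2 alone, as a 5530 bp peak with a score of 1167. Replicate 1 had 2 peaks there, and the higher-scoring one was 457 bp wide with a score of 72.0.

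Whether the 2 libraries found the same sites was asked by overlap. Of the replicate 1 peaks, 588 of 2065 (28.5%, 95% interval 26.5 to 30.5%) were overlapped by a replicate 2 peak, and of the replicate 2 peaks 554 of 1427 (38.8%, 36.3 to 41.4%) by a replicate 1 peak. Circular shifts gave 1.45% and 1.97%, so the observed overlaps were 19.6 and 19.7 times chance. The highest of the 1000 shifts reached 2.71% and 3.43% (one-sided permutation p = 0.001 for both, the smallest the shifts can give; adjusted p = 0.0016). Most peaks of either library were thus without a partner in the other. Shared peaks were wider than unshared ones, with a median of 394 against 268 bp in replicate 1 and 587 against 383 bp in replicate 2 (permutation test of ranks, p = 1e-05 for each, adjusted p = 2.7e-05). An overlap of 1 bp is easier to meet for a wider peak, so part of this difference may follow from the rule.

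The highest-scoring peaks were the ones most often shared. With each list divided by score into 5 groups of equal size, overlap in replicate 1 was 16.0% (12.6 to 19.9%) in the lowest group and 52.5% (47.6 to 57.4%) in the highest. In replicate 2 it was 31.5% (26.1 to 37.2%) and 65.6% (59.8 to 71.1%). In replicate 2 the intervals of the lower 4 groups overlapped one another, and the highest group stood above them. The highest group also held wider peaks than the lowest, with medians of 785 against 170 bp in replicate 1 and 730 against 232.5 bp in replicate 2. Wider peaks meet the 1 bp rule more easily, and score was not separated from width. Peaks of 2 kb or more were overlapped in 25 of 38 cases in replicate 1 (65.8%, 48.6 to 80.4%) and 37 of 50 in replicate 2 (74.0%, 59.7 to 85.4%). Across 543 pairs of shared peaks, scores in the 2 libraries were correlated with Spearman's rho of 0.47 and Pearson's r of 0.46 (permutation p = 1e-05 for each, adjusted p for rho 2.7e-05). These correlations are across peaks, which are not independent replicates, and scores tied at 3100 limit them at the top.

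**Figure D1:**
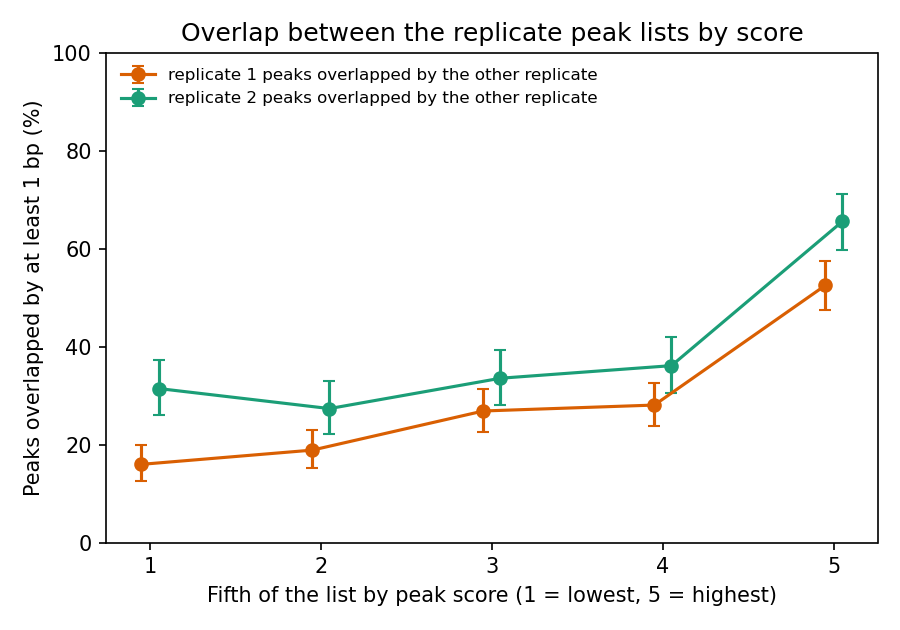
Share of peaks of each replicate list (percent, y axis) overlapped by at least 1 bp by a peak of the other replicate, by group of the list in order of score (x axis, 1 lowest, 5 highest). Points are shares and bars exact 95% binomial intervals, and the highest group stands above the others, at 52.5% in replicate 1 and 65.6% in replicate 2.

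The series-wide list was neither the union nor the intersection of the replicate lists. Of its 3380 nuclear peaks, 570 (16.9%) overlapped both replicate lists, 788 (23.3%) replicate 1 only, 805 (23.8%) replicate 2 only, and 1217 (36.0%) neither. Peaks in both had a median score of 18.4 and a median width of 484 bp. Peaks in neither had a median score of 4.83 and a median width of 196 bp. Peaks in both were wider than all others of the list, whose median was 238 bp (permutation test of ranks, p = 1e-05, adjusted p = 2.7e-05). The classes were set by the 1 bp rule, which wider peaks meet more easily, so part of this difference may follow from the rule. The list held 1326 of the 1427 replicate 2 peaks (92.9%, 91.5 to 94.2%) and 1342 of the 2065 replicate 1 peaks (65.0%, 62.9 to 67.1%).

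All 6 nuclear chromosomes carried SMC-6 peaks, and no excess on X was detected. In the series-wide list the density was highest on chromosomes I (40.4 peaks per Mb) and III (39.8), and lowest on V (24.3). Replicate 2 had the same order except that III (19.7 peaks per Mb) stood above I (16.1), and its lowest density was also on V (11.4). Replicate 1 departed from that order, with the highest density on IV (24.6) and the lowest on III (17.8). Chromosome III took 15.5% ± 5.09 of the peaks (SD, n = 2 libraries) and IV 17.7% ± 4.42. The others lay at 16.0% ± 1.39 for I, 15.3% ± 1.38 for II, 18.1% ± 2.08 for V and 17.3% ± 1.39 for X. The order of these spreads depends on the scale: in peaks per Mb, which also carries the difference in list size, III had the smallest SD (1.39) and IV the largest (8.97). With 2 libraries these differences between chromosomes were not tested.

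Condensin of the dosage compensation complex, another SMC complex, gathers on X in hermaphrodites, and the same comparison of X with the autosomes was made for SMC-6. The series-wide list had 35.8 peaks per Mb on X and 33.3 on the autosomes, a ratio of 1.08 (95% interval 0.954 to 1.21, permutation p = 0.29, adjusted p = 0.35). Replicate 1 gave 0.909 (0.754 to 1.08, permutation p = 0.33) and replicate 2 gave 1.04 (0.910 to 1.20, p = 0.68). The replicate ratios did not differ by more than the block-to-block spread (quotient 0.871, 0.711 to 1.06, permutation p = 0.27). An excess on X within these intervals is not excluded, and by covered bases in place of peaks the upper bound for the series-wide list was 1.43.

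Along the autosomes the 2 libraries differed. With each autosome divided into 3 parts of equal length, replicate 1 peaks were denser in the left and right parts (the ends), with 22.9 peaks per Mb against 17.1 in the middle part (the centre), a ratio of 1.34 (1.10 to 1.64, permutation p = 5.7e-04, adjusted p = 0.0013). Replicate 2 peaks were denser in the centres, with 13.1 peaks per Mb at the ends against 16.2, a ratio of 0.804 (0.669 to 0.960, permutation p = 0.024, adjusted p = 0.035). The quotient of the ratios was 1.67 (1.35 to 2.07, permutation p = 1e-05, adjusted p = 2.7e-05). Blocks were treated as independent, and larger blocks were tried for the series-wide list only. If neighbouring blocks were alike, these intervals are too narrow and these p-values too small. The replicate 1 ratio lay above the replicate 2 ratio on each of the 5 autosomes, most on II (1.92 against 0.650) and least on IV (1.23 against 0.986). In the series-wide list ends and centres had 33.1 and 33.6 peaks per Mb (ratio 0.985, 0.864 to 1.12, permutation p = 0.82). The replicate 2 call was lost without II (ratio 0.842, permutation p = 0.10), III (0.826, p = 0.069) or V (0.830, p = 0.084). These ratios lay within the interval of the replicate 2 ratio over all 5 autosomes, so fewer blocks alone could have lost the call. The quotient passed without any of the 5, at its lowest 1.47 without II (permutation p = 9.8e-04). On X the ratio was 1.38 (1.02 to 1.91, permutation p = 0.083) in replicate 1, where the bootstrap interval leaves out 1 and the permutation test did not pass, and 1.06 (0.863 to 1.29, p = 0.64) in replicate 2.

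**Figure D2:**
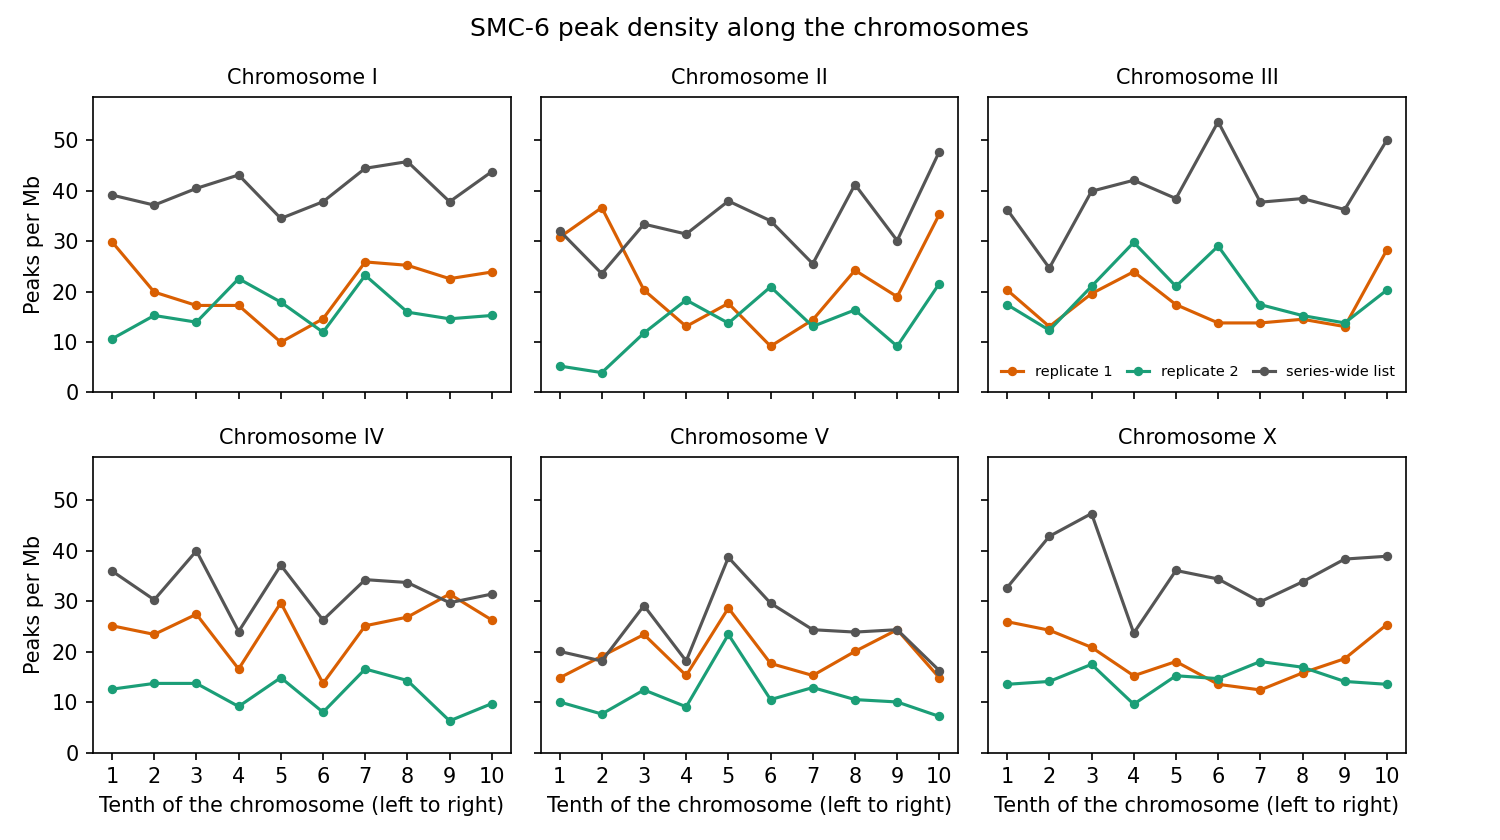
Peaks per Mb (y axis) in 10 parts of equal length of each of the 6 nuclear chromosomes, from left to right (x axis), with 1 line per list: replicate 1, replicate 2 and the series-wide list. On chromosome II replicate 1 had 36.6 peaks per Mb in part 2, where replicate 2 had 3.93.

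Replicate 1 peaks overlapped by replicate 2 had a ratio of 0.748 (0.560 to 1.01), and the same sites taken from the replicate 2 list had 0.754 (0.570 to 1.01). Replicate 1 peaks without a partner had a ratio of 1.75 (1.40 to 2.21, permutation p = 1e-05). Replicate 2 peaks without a partner stood at 0.838 (0.665 to 1.05). Shared sites cannot differ between the lists, and having a partner depends on the density of the other list, so this split does not locate the difference between the libraries. Among replicate 1 peaks of 53 to 175 bp, the narrowest of 5 groups by width, the ratio was 1.96 (1.49 to 2.73). It was 1.09 (0.837 to 1.44) among those of 369 to 605 bp, an interval that does not overlap the former, and 1.15 (0.766 to 1.79) among those of 609 bp and more, one that does. In replicate 2 the ratio was 1.00 (0.770 to 1.31) in the narrowest group and 0.669 (0.454 to 0.985) in the widest. Differences between width groups were not tested.

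**Figure D3:**
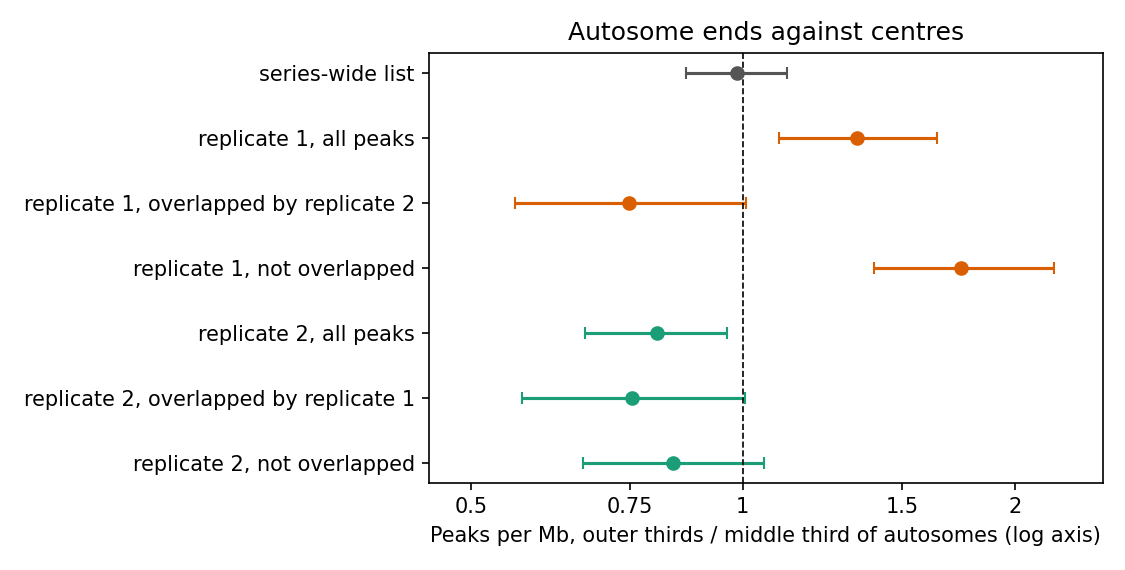
Ratio of peaks per Mb at the ends to that in the centres of the 5 autosomes (x axis, log scale), for each list and for the replicate peaks with and without a partner in the other replicate (rows). Points are ratios, bars 95% block bootstrap intervals and the dashed line a ratio of 1, and replicate 1 peaks without a partner stand at 1.75, and replicate 1 and replicate 2 peaks with one at 0.748 and 0.754.

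Called SMC-6 peaks lay closer to one another than under random placement. In the series-wide list 2160 of 3380 peaks (63.9%) had a neighbour within 10 kb, against 50.1% under random placement and at most 54.3% in 1000 placements (permutation of peak positions, one-sided p = 0.001, the smallest they can give; adjusted p = 0.0016). Of the series-wide peaks found in both replicates, 39.5% had such a neighbour against 10.9% by chance, 3.62 times the chance level, which is lower for shorter lists. These peaks were chosen by overlap with replicate peaks, so pieces lying within 1 wide replicate peak were kept together. Random placement has no such pieces, and this ratio does not show that separate sites lie in groups. Replicate 1 stood at 60.1% against 34.2% and replicate 2 at 44.1% against 25.6%. Gaps of 500 bp or less made up 18.6% of the gaps between neighbours in replicate 1, 9.43% in replicate 2 and 14.2% in the series-wide list. A wide enriched region that a caller divides adds such neighbours. Merging peaks under 1 kb apart left 517 of 635 series-wide peaks on X and 2223 of 2745 on the autosomes. The ratio to chance was 1.72 with a window of 5 kb, 1.28 with 10 kb and 1.06 with 20 kb. Clustering was not tested on merged peaks, so divided regions may supply much or all of the excess.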

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

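Peaks on the mitochondrial genome lay outside the comparisons between nuclear chromosomes. The series-wide list held 12 of them, covering 9786 bp with scores of 14.7 to 94.8. Replicate 2 held 3 mitochondrial peaks covering 13186 bp with scores of 2744 to 3100, and replicate 1 held 3 covering 3153 bp with scores of 148 to 1244. Input signal on this genome was not analysed here.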

How the results depend on the processing

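Leaving out each autosome in turn was chosen after the data were seen, and the other alternatives before. Of 74 alternative values, 59 kept their direction and side of the threshold or stayed within the replicate spread. For shares per chromosome that spread was the SD of the 2 replicate lists, which were also among the alternatives. It was widest where the libraries disagreed most, so staying within it does not show that a share was stable. Both replicate overlaps (19.3 to 33.8% and 27.9 to 38.5% over the alternatives), the score correlation (rho 0.42 to 0.64) and the clustering (1.06 to 3.62 times chance) passed under every alternative run for them. No alternative for clustering merged neighbouring peaks first. The ratio of X to autosome density, not past the threshold in any list, fell below 1 among peaks in both replicate lists (0.979), and was 0.909 to 1.04 with 1 replicate list alone. The ratio of ends to centres was 0.804 in replicate 2 alone and 1.34 in replicate 1 alone, each past the threshold, so the 2 libraries disagreed in direction. The series-wide ratio of 0.985 was not past the threshold. With blocks of 1 Mb it was 1.00, above 1 by less than its interval. The share of peaks on chromosome I was 15.1 to 17.0% with 1 replicate list alone against 18.02% in the series-wide list. For V it was 16.7 to 19.6%, and 20.7% for peaks in both lists, against 15.0%. For X it was 16.3 to 18.3%, and 17.4% for peaks in both, against 18.8%. For III it was 11.9% with replicate 1 alone and 19.1% with replicate 2 alone against 16.2%. For IV it was 20.8% and 14.6% against 16.7%. Those of III and IV counted as within the replicate spread. Median width was 298 to 446 bp with 1 replicate list alone and 484 bp for peaks in both, against 266 bp. The cause of these shifts was not tested. Without each autosome in turn, the quotient of the replicate ratios of ends to centres was 1.47 to 1.77, past the threshold each time, while the replicate 2 ratio lost its call without II, III or V. Alternatives for start sites, gene features, non-coding RNA genes, gene lists and base composition were not run. Read depth is not known from the lists, so differences in the number and width of peaks between libraries cannot be set against it. No paired analysis was possible because no input peak list or signal was analysed, so the replicate numbers shared by input and ChIP pair no values.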

Other observations

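Of the tests in this part, those on short replicate 1 peaks, on autosome centres and on weak signal at right ends were set before their results were seen, and the others after. The widest peak of any list, chosen after its value was seen, was a replicate 1 peak of 11914 bp at 17120473 to 17132386 on chromosome V, the chromosome whose right arm carries the tandem 5S ribosomal RNA genes. Replicate 2 covered nearly the same stretch with peaks of 7890 and 4499 bp, and the series-wide list divided it into 6 peaks with scores of 49.96 to 55.16. Without an annotation of the same build the position of those genes was not compared with it. Input signal there was not analysed, so an effect of reads from repeats cannot be told apart from binding.

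Runs of peaks linked by gaps of at most 10 kb were also counted. Their number under random placement was not computed, and a wide region that a caller divides can make a run. In the series-wide list 73 runs held 5 or more peaks, and 10 held 10 or more. The largest, 23 peaks over 30.4 kb, lay on X at 4025977 to 4056391, yet only 3 of its peaks overlapped replicate 1 and 2 overlapped replicate 2. A run of 19 peaks on III at 7406072 to 7448094 had 11 peaks in replicate 2 and 0 in replicate 1, and one of 13 peaks on IV at 682867 to 706622 had 10 in replicate 1 and 1 in replicate 2. By contrast, 10 of the 11 peaks of a run on II at 13817470 to 13836065 overlapped each replicate list. Some of the strongest peaks, chosen after their values were seen, had no partner in the other library, such as a 4742 bp replicate 1 peak on IV at 14210731 to 14215472 and a 4918 bp replicate 2 peak on III at 2496955 to 2501872, both with a score of 3100.

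Replicate 1 peaks lay more toward autosome ends than replicate 2 peaks. Weak peaks near the calling threshold are argued against as the whole cause only so far as they lie in the lower 50% of each list by score. In the upper 50% the quotient of the end to centre ratios was 1.84 (1.44 to 2.39). The median score was 94.62 in replicate 1 and 153.83 in replicate 2, so the 2 upper parts were not cut at a common score. Short peaks of replicate 1 are argued against only as the whole cause of the difference, since among peaks of at least 400 bp the quotient was 1.59 (1.20 to 2.15). The replicate 1 ratio itself was 1.11 there and the replicate 2 ratio 0.697. The quotient therefore does not speak against short peaks as the source of the replicate 1 excess at the ends. Peaks called in replicate 1 alone had a ratio of 1.75 against 0.748 for those with a partner, but shared sites are the same in both lists, so whether these peaks are the source cannot be told apart from a lower replicate 2 density at the ends. A difference in embryo stages between preparations, in the input used for each call or in reads from repeats, which are frequent on autosome arms, may lie behind it; these stay open, and no biological explanation was tested.

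The series-wide list held a larger share of replicate 2 peaks (92.9%) than of replicate 1 peaks (65.0%). Lower scores in replicate 1 account for part of this at most: after weighting replicate 1 peaks to the scores of replicate 2, which assumes 1 scale for both lists, the difference fell from 27.9 to 19.2 percentage points (17.0 to 21.4). The position of replicate 1 peaks toward chromosome ends is not the whole cause either, since in the autosome centres the difference was 20.7 points (16.22 to 24.98). How the libraries were joined and scaled stays open. No biological explanation was tested.

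Chromosome ends carry telomeric repeats, and left ends held a peak within 1 kb on all 6 chromosomes in all 3 lists, right ends on 6 in the series-wide list and on 1 in each replicate list, where a slightly wider window would add chromosome I, whose last replicate peaks end at 15071349 and 15071351. With ends set by the WS220 chromosome lengths, taken from general knowledge of that assembly and not from the lists, random placement is excluded for the series-wide list, as 10000 placements gave at most 4 of the 12 ends (permutation of peak positions, one-sided p = 1e-04, the smallest they can give). Weak signal at right ends is argued against, since none of the 6 outermost right peaks (scores 8.22 to 38.11) overlapped a replicate peak while 94% of series-wide peaks of similar score did, and each of 10000 matched draws had at least 4 of 6 overlapped (0.010%, the smallest share that so many draws can give). The match was on the series-wide score alone, so this holds only if that score measures signal at the last bases as it does elsewhere. That the caller versions treat the last bases differently may explain the asymmetry and cannot be told apart from other differences between the lists, since the series-wide list alone came from MACS v2 and at most 1 right end had a peak within 1 kb in a replicate list. The outermost series-wide peaks ran 30 or 31 bases past those lengths, and no biological explanation was tested. Input signal at the chromosome ends was not analysed, so an effect of reads from telomeric repeats cannot be told apart from binding.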
